A study of Homo sapiens with 6 samples.

How the data were processed

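RNA-seq gene expression was studied in 6 libraries of HK-2 cells, an established line of human renal proximal tubule epithelium. All 6 came from cells transfected with an overexpression plasmid for a long noncoding RNA (lncRNA), which the sample titles call LncR2. The labels give 3 libraries as exposed to the platinum drug cisplatin for 0 h and 3 for 24 h. Per the labels' protocols, total RNA was treated with DNase, ribosomal RNA (rRNA) was depleted with a commercial kit, and directional libraries were sequenced as paired ends on an Illumina HiSeq instrument.

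A table of read counts per gene and a table of FPKM were used. The deposited read counts are whole numbers with 28565 genes, and their totals differ between libraries. The deposited FPKM values have 28561 genes and are rounded to hundredths, and the 4 genes missing from that table were used in the counts alone. Per the submitters' processing notes, bcl2fastq, TopHat2, edgeR and the genome build GRCh38 were used. Their versions, the read counter, the annotation release, the use of strand in counting and the rule for reads that map to several places are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense partners are therefore uncertain, because the counting may have split or pooled their reads.

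Gene identifiers were matched without their version to GENCODE 29 (GRCh38), which gave the positions and lengths of 27925 genes (97.8%). Of all genes in the count table, 85.5% had the same version in GENCODE 29. Gene symbols and gene types are those of the count table. Loci of the nuclear rRNA genes were taken from a RefSeq annotation of the same genome, on chromosome 21 only. No gene of the table carried a name of the XLOC series, so the lncRNA in the series title was not analysed here. Every row of the table named a gene, so 0 rows were left out for that reason.

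The total count per library was 5039050, 5028881 and 5844246 in 0 h replicates 1, 2 and 3 and 6022268, 7018785 and 7248754 in 24 h replicates 1, 2 and 3. Reads were counted without molecular identifiers. The errors given for fold changes hold both the spread between libraries and counting error, which weighs most in genes with few counts. The labels do not say whether the 3 libraries of a group came from separate cultures, and the design text of the series speaks of 2 biological replicates per treatment. P-values therefore rest only on the spread between these libraries, counting error included.

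The 3 libraries at 24 h were compared with the 3 at 0 h by edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM scaling, the default filterByExpr filter and no covariates. P-values were adjusted by Benjamini-Hochberg over the 13389 genes tested, and genes with an adjusted p under 0.05 were called. The common biological coefficient of variation was 0.103. Fold changes are log2 of 24 h over 0 h, given ± the standard error of the model with n = 3 libraries per group. Levels are CPM of TMM-scaled library totals, as mean ± SD over 3 libraries, except that the levels given for whole lists of other cell types use the totals without TMM.

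Gene lists for 22 pathways and functions, and 3 lists of markers of other cell types, were fixed before the data were examined, as were the test, the design, the gene-naming rule and the main alternatives. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists. Camera with an estimated correlation and fry were run beside it. Members were counted by the edgeR test, adjusted over all genes and also adjusted over the list alone.

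The genes named were TNF, the 5 largest rises and the 5 largest falls, the 2 members with the smallest p in each tested list, and the 2 most abundant members of each list of other cell types. Of the genes this rule takes, 1 is not reported here. The largest changes were taken among called genes with a symbol other than a clone or locus name, a mean of at least 5 CPM and no overlap between the groups, which chance gives for 10% of genes with 3 libraries against 3. Other genes are named as examples within lists, or are said to have been chosen after their values were seen. The relation of fold change to gene span was Spearman's rho across genes, which are not independent replicates.

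Each gene's count divided by its FPKM is proportional to its length and to the total by which the authors scaled that library. Those totals, called FPKM denominators, were recovered from genes with 1 annotated transcript and more than 300 counts. Values of single measures were compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 libraries against 3.

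Alternatives fixed in advance were RLE, upper-quartile and total-count scaling, other filters on low counts, robust dispersion, DESeq2 1.42.0, limma on log2(FPKM + 1), the replicate number as a block, a correction for gene length, removal of the 10 most abundant genes, a 2-fold minimum and leaving out each library. Added after seeing the data were a GC correction of each library, protein-coding genes alone, removal of both libraries numbered 3, and scaling by the FPKM denominators.

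The steps were tested on simulated data for this comparison, with 13210 simulated genes tested of which 196 were changed. The edgeR test recovered 42.4% of genes changed 1.5-fold and 83.5% of those changed 2-fold, and 7.52% of its calls were false. A list simulated at 1.3-fold was found and 0 of the other lists were called. Genes were simulated independently of each other, whereas the correlation that camera estimated in the real lists reached 0.809. The simulation therefore does not test the list calls where members are correlated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps. Cells with the negative-control plasmid and cells kept for 24 h without cisplatin were not analysed here.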

Results

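The data are 6 RNA-seq libraries of HK-2 renal tubule cells that carried an lncRNA overexpression plasmid, 3 at 0 h and 3 at 24 h of cisplatin, a drug that crosslinks DNA. Total counts ran from 5028881 to 5844246 per library at 0 h and from 6022268 to 7248754 at 24 h. The series concerns cisplatin-induced death of tubular cells and the cytokine TNF, and the comparison asks which RNAs differ after 24 h of cisplatin in cells with the plasmid. It does not measure the effect of the lncRNA, and it does not separate cisplatin from time after transfection, because control cells were not analysed here.

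After 24 h of cisplatin, 11 of 24 genes of the integrated stress and unfolded protein response and 13 of 26 genes of G2/M and mitosis fell, and 5 of 28 genes of G1/S and DNA replication rose (0 of them without 0 h replicate 2). Camera called these 3 lists at its preset correlation, and the calls were lost, with Benjamini-Hochberg adjusted p = 0.123, 0.123 and 0.164 with an estimated correlation. At the preset correlation camera called 6 lists in all, but also up to 7 when libraries of both times were mixed in each group. Of 21 TNF and NF-kB targets, 4 rose, the cytokine genes IL6, CXCL2, CXCL3 and CSF2 (1 of the list without 24 h replicate 2), in a list that camera did not call. Of 13389 genes tested, 116 rose and 278 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 6 of the rises and 98 of the falls were at least 2-fold. Protein-coding genes held 114 of the rises and 223 of the falls. Tested alone, protein-coding genes gave 6 rises and 61 falls of at least 2-fold. The largest falls under the naming rule were those of TEX101, a germ-cell surface protein (-2.23 ± 0.30 on the log2 scale), INHBE, an activin subunit (-2.17 ± 0.18), and SLC6A9, the glycine transporter GLYT1 (-2.11 ± 0.22). PIF1, a DNA helicase, fell by 1.69 ± 0.30 and QRICH2, a sperm flagellum protein, fell by 1.67 ± 0.27. INHBE went from 20.7 ± 1.80 to 4.61 ± 0.440 CPM (mean ± SD, n = 3 each), whereas TEX101 varied more, from 70.9 ± 28.8 to 15.3 ± 8.10 CPM.

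The largest rises were those of CRACR2B, a regulator of calcium release-activated channels (1.22 ± 0.24), the chemokine CXCL3 (1.13 ± 0.22), HCFC1R1, a partner of host cell factor C1 (1.10 ± 0.18), MAPK8IP2, a scaffold of JNK signalling (1.09 ± 0.14), and P2RY6, a receptor for UDP (1.09 ± 0.28). MAPK8IP2 went from 20.5 ± 3.37 to 43.7 ± 4.07 CPM (mean ± SD, n = 3 each). In GENCODE 29 on GRCh38, INHBE lies on chromosome 12 from 57452323 to 57459280, TEX101 on chromosome 19 from 43401496 to 43418597, SLC6A9 on chromosome 1 from 43991500 to 44031467, MAPK8IP2 on chromosome 22 from 50600685 to 50613981 and CXCL3 on chromosome 4 from 74036589 to 74038807. The identifiers of these 5 genes are ENSG00000139269.2, ENSG00000131126.18, ENSG00000196517.11, ENSG00000008735.13 and ENSG00000163734.4. Without 1 library, the calls of HCFC1R1, MAPK8IP2, TEX101, INHBE, SLC6A9 and QRICH2 held in all 6 fits, whereas CRACR2B and CXCL3 were lost without 0 h replicate 2 or 24 h replicate 2, PIF1 without 24 h replicate 2, and P2RY6 without 0 h replicate 2 or any library at 24 h. TEX101 was not called with robust dispersion, and P2RY6 was not called by DESeq2.

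The counts of called genes changed when single libraries were left out. Leaving out 0 h replicate 2 gave 24 rises and 103 falls, 24 h replicate 2 gave 21 and 92, 24 h replicate 3 gave 52 and 134, 24 h replicate 1 gave 58 and 204, and 0 h replicate 3, which stood apart on the second principal component (-30.4, against 8.50 and -1.48 in 0 h replicates 1 and 2), gave 574 and 923. Of these, 20 rises and 257 falls were at least 2-fold without 0 h replicate 3, 2 and 52 without 0 h replicate 2, 3 and 47 without 24 h replicate 2 and 6 and 57 without 24 h replicate 3. On the first principal component (39.3% of the variance), 0 h replicate 3 was at 1.28. It lay nearer to 24 h replicate 1 (6.29) than to 0 h replicates 1 and 2 (-23.8 and -24.5). Rises made up 29.4% of the calls with TMM, 46.6% with no filter on low counts (345 and 395), 40.5% with a GC correction of each library, and 92.3% when libraries were scaled by the FPKM denominators, which moved the median of all genes by 0.24 on the log2 scale and gave 2354 rises and 195 falls. Changes are therefore given relative to the median gene, and limma on log2(FPKM + 1) also gave 92.3% rises with a shift of 0.18.

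**Figure D1:**
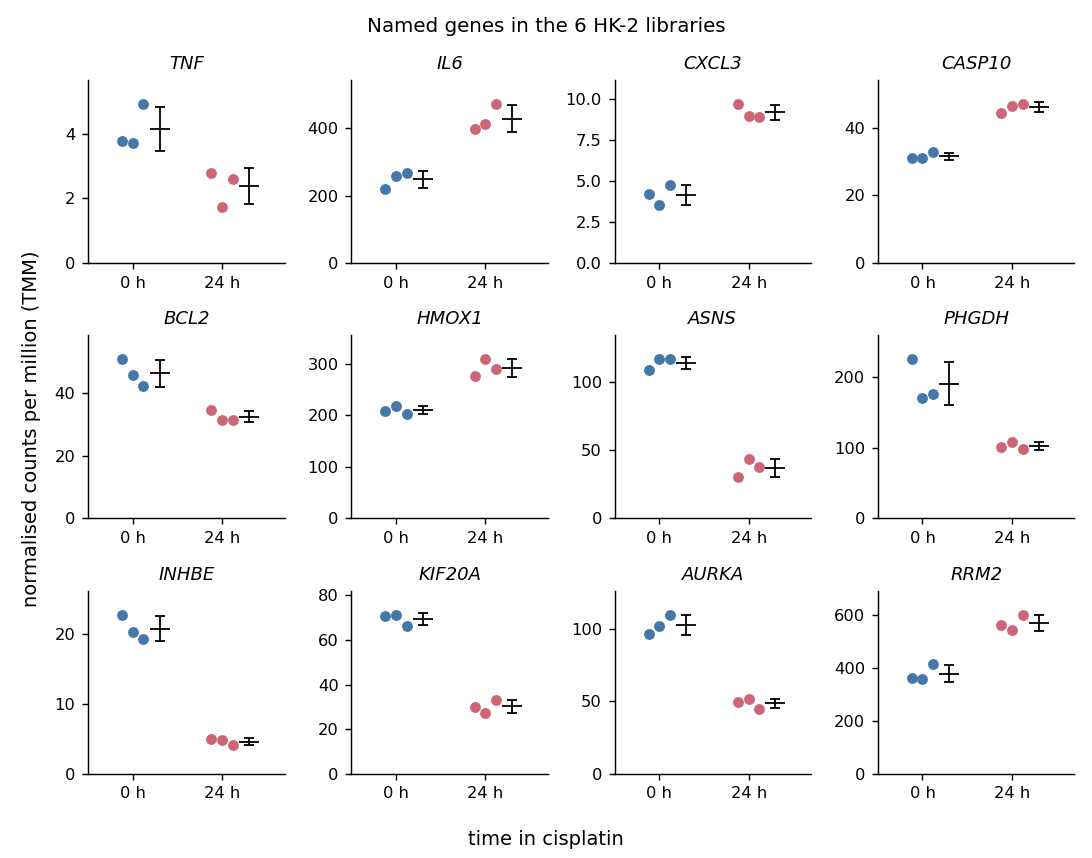
TMM-scaled CPM of 12 named genes in the 3 libraries at 0 h and the 3 at 24 h of cisplatin, as single libraries (points) with mean and SD (bars). All genes but TNF were called, and TNF, at 3.79, 3.72 and 4.94 at 0 h and 2.80, 1.74 and 2.61 at 24 h, was not.

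The list of the integrated stress and unfolded protein response holds genes that supply amino acids and chaperones when protein synthesis is stressed. Of the 24 tested, 11 fell, 0 rose and 13 did not pass (adjusted over the list alone, 15 fell and 1 rose). ASNS, asparagine synthetase, fell by 1.62 ± 0.12 on the log2 scale, from 114 ± 4.45 to 37.0 ± 6.47 CPM (mean ± SD, n = 3 each). PHGDH (-0.89 ± 0.12) and PSAT1 (-0.70 ± 0.10), of serine synthesis, CHAC1, which degrades glutathione (-1.32 ± 0.21), and SLC7A11, the cystine transporter (-0.69 ± 0.09), also fell. The other falls were those of the transcription factor DDIT3 (CHOP), its partner TRIB3, XBP1, HERPUD1, DDIT4 and SESN2, with values from -0.77 to -0.39. Values that did not pass were -0.27 ± 0.11 for ATF4, the transcription factor of this response, and -0.11 ± 0.10 for the chaperone HSPA5.

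The median of this list was -0.36 and was called by camera (Benjamini-Hochberg adjusted p = 1.72e-16) and fry (adjusted p = 0.0210), with adjusted p = 0.123 with an estimated correlation. Scaled by the FPKM denominators the median stayed below 0, at -0.12, with 7 falls and 2 rises. The 11 falls became 7 without 0 h replicate 2 and 6 without 24 h replicate 3, and ASNS, PHGDH and SLC7A11 were called in all 6 fits without 1 library.

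Of the 26 genes of G2/M and mitosis, 13 fell and 0 rose (adjusted over the list alone, 20 fell). KIF20A, a kinesin of cytokinesis, fell by 1.20 ± 0.11 on the log2 scale, from 69.5 ± 2.72 to 30.2 ± 2.92 CPM (mean ± SD, n = 3 each). The mitotic kinases AURKA (-1.08 ± 0.11) and PLK1 (-0.79 ± 0.10), the cyclin CCNB1 (-0.82 ± 0.10) and the kinetochore motor CENPE (-0.89 ± 0.12) also fell. Of the 28 genes of G1/S and replication, 5 rose and 0 fell (adjusted over the list alone, 13 rose). These were RRM2, a subunit of ribonucleotide reductase (0.59 ± 0.10), the transcription factor E2F1 (0.59 ± 0.11), TYMS, thymidylate synthase (0.45 ± 0.10), and the replication-licensing and helicase factors CDT1 (0.47 ± 0.11) and CDC45 (0.47 ± 0.12).

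Camera called the mitotic list (median -0.49, Benjamini-Hochberg adjusted p = 9.48e-27) and the G1/S list (median 0.29, adjusted p = 8.99e-10), fry gave adjusted p = 0.0210 for both, and the values were adjusted p = 0.123 and 0.164 with an estimated correlation. Scaled by the FPKM denominators the medians were -0.25 and 0.53, with 7 falls and 1 rise among the mitotic genes and 22 rises among the G1/S genes. The 13 mitotic falls became 7 without 0 h replicate 2, 24 h replicate 1 or 24 h replicate 2, and the 5 rises became 0 without 0 h replicate 2, 2 without 24 h replicate 1, 1 without 24 h replicate 2, 2 without 24 h replicate 3 and 12 without 0 h replicate 3. With the GC correction 19 mitotic genes fell and 10 G1/S genes rose. These counts were 18 and 9 without both libraries numbered 3, and 12 and 10 with no filter on low counts. KIF20A and AURKA passed in all 6 fits without 1 library, RRM2 was lost without 0 h replicate 2, and E2F1 without 0 h replicate 2 or 24 h replicate 2.

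TNF, the cytokine named in the series title, was low at both times, with 19, 19 and 28 counts at 0 h and 17, 12 and 19 at 24 h. Its level was 4.15 ± 0.686 CPM at 0 h and 2.38 ± 0.568 CPM at 24 h (mean ± SD, n = 3 each), a log2 fold change of -0.81 ± 0.30 with a 95% interval from -1.45 to -0.16. It did not pass the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.167), and its adjusted p ran from 0.0707 to 0.488 over the alternatives. TNF (ENSG00000232810.3) lies on chromosome 6 from 31575567 to 31578336.

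Of the 21 genes tested in the list of TNF and NF-kB targets, TNF included, 4 rose and 0 fell (adjusted over the list alone, 5 rose). IL6, an inflammatory cytokine, rose by 0.78 ± 0.11 on the log2 scale, from 249 ± 25.1 to 428 ± 39.3 CPM (mean ± SD, n = 3 each), with the chemokines CXCL3 (1.13 ± 0.22) and CXCL2 (0.57 ± 0.11) and the growth factor CSF2 (0.45 ± 0.11). CXCL2 and CXCL3 are close paralogs, so their values are uncertain. Other cytokine genes of the list did not pass, with CXCL8 at 0.47 ± 0.13, CCL2 at -0.18 ± 0.31, CCL20 at -0.13 ± 0.17 and LIF at -0.08 ± 0.11, nor did the feedback inhibitor NFKBIA (0.17 ± 0.10) or the adhesion receptor ICAM1 (-0.21 ± 0.11). The list's median was -0.09 while its mean was 0.05 and camera's direction was up (Benjamini-Hochberg adjusted p = 0.243), and with the FPKM denominators the median was 0.14 and 6 rose. The 4 rises became 2 without 0 h replicate 2 and 1 without 24 h replicate 2, and IL6 was called in all 6 fits without 1 library.

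Of 22 receptors and adaptors of TNF signalling tested, 0 were called by edgeR (also 0 adjusted over the list alone), 4 had an unadjusted p under 0.05, and DESeq2 called 1. Without 0 h replicate 3, 1 rose, with the FPKM denominators 6 rose, and 4 rose by limma on log2(FPKM + 1). The smallest p-values were those of TNFRSF1A, the main TNF receptor (0.34 ± 0.10), and RNF31, a ubiquitin ligase of the receptor complex (0.35 ± 0.16).

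Targets of p53, which DNA damage activates, went both ways and few passed. Of 28 tested, 1 rose and 2 fell (the same counts adjusted over the list alone): PLK2, a stress kinase (0.40 ± 0.10), against SESN2 (-0.77 ± 0.15) and the stress cytokine GDF15 (-0.46 ± 0.12). SESN2 is also a member of the list of the integrated stress and unfolded protein response, so its fall is not particular to p53 targets. The cell-cycle inhibitor CDKN1A (p21) was at 0.20 ± 0.11 with a 95% interval from -0.04 to 0.44, and MDM2, the ligase of p53, at -0.16 with an interval from -0.38 to 0.06. Camera gave Benjamini-Hochberg adjusted p = 0.787. With the FPKM denominators 8 rose and 1 fell. Without 0 h replicate 2 or 24 h replicate 3, 0 members were called, PLK2 was kept only without 0 h replicate 3, and SESN2 was lost without 0 h replicate 2 or 24 h replicate 3.

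In the BCL2 family and caspases, 1 of 27 rose and 1 fell (the same adjusted over the list alone). CASP10, an initiator caspase, rose by 0.54 ± 0.11 on the log2 scale, from 31.6 ± 1.04 to 46.0 ± 1.48 CPM, and BCL2, an inhibitor of apoptosis, fell by 0.51 ± 0.12, from 46.3 ± 4.34 to 32.4 ± 1.77 CPM (mean ± SD, n = 3 each). The list was not called by camera (Benjamini-Hochberg adjusted p = 0.589), and 4 members had an unadjusted p under 0.05. CASP10 was lost without 0 h replicate 2, 24 h replicate 2 or 24 h replicate 3, and BCL2 without any library other than 0 h replicate 3, without which 3 members rose and 3 fell. With the FPKM denominators 8 members rose and BCL2 was not called.

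Of 23 targets of NRF2, the regulator of antioxidant genes, 2 rose and 1 fell (adjusted over the list alone, 5 rose and 1 fell). HMOX1, heme oxygenase, rose by 0.47 ± 0.10 on the log2 scale, and SLC7A11, which the stress list also holds, fell. The median was 0.20 (0.44 with the FPKM denominators, where 14 rose), camera's Benjamini-Hochberg adjusted p was 2.59e-04 and fry's was 0.0210, with adjusted p = 0.151 with an estimated correlation. The rises were 0 without 0 h replicate 2, 24 h replicate 2 or 24 h replicate 3, 1 without 24 h replicate 1, and 7 without 0 h replicate 3.

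Of 13 mitochondrially encoded mRNAs, 0 were called by edgeR. Adjusted over the list alone 7 fell, 9 had an unadjusted p under 0.05, and DESeq2 called 0. The median was -0.33 (-0.10 with the FPKM denominators, where 1 gene rose), and camera called the list (Benjamini-Hochberg adjusted p = 2.59e-04), but fry did not (adjusted p = 0.289), nor did camera, at adjusted p = 0.737 with an estimated correlation. MT-ND4L (-0.58 ± 0.18) and MT-ATP6 (-0.35 ± 0.12), of respiratory complex I and ATP synthase, had the smallest p-values and overlap neighbouring genes, so their values are uncertain. Leaving out 0 h replicate 1 gave 4 falls and 0 h replicate 3 gave 1, and camera's call was lost without both libraries numbered 3 (adjusted p = 0.110).

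Replication-dependent histones, whose near-identical copies make them uncertain, went both ways, and of 17 tested 1 rose and 1 fell (adjusted over the list alone, 3 rose and 2 fell). The linker histone HIST1H1D fell by 1.31 ± 0.17 and HIST1H3B rose by 0.51 ± 0.11 on the log2 scale. The median was 0.05 while the mean was -0.02, and camera's direction was up with a Benjamini-Hochberg adjusted p of 0.910, 0.0336 without 0 h replicate 3 and 0.0488 without both libraries numbered 3, and with the FPKM denominators 6 rose and 1 fell. HIST1H3B was kept only without 0 h replicate 3 or 24 h replicate 1, HIST1H1D was called in all 6 fits without 1 library, and 4 of the list rose without 0 h replicate 3.

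Among TGF-beta, matrix and mesenchymal genes 1 of 25 fell and 0 rose (the same adjusted over the list alone, 7 with an unadjusted p under 0.05). COL5A1, a fibrillar collagen, fell by 1.04 ± 0.25 on the log2 scale, from 6.01 ± 0.562 to 2.92 ± 0.155 CPM (mean ± SD, n = 3 each), and CYR61, a matricellular protein, was at 0.31 ± 0.09. COL5A1 was lost without any library other than 0 h replicate 3, without which 3 of the list fell, and DESeq2 did not call it but called 1 other gene of the list as higher. With the FPKM denominators 6 of the list rose and 1 fell.

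The kidney-injury list had 0 of 17 called by edgeR (1 higher and 1 lower adjusted over the list alone, 4 with an unadjusted p under 0.05, 1 by DESeq2). SOX9, a regulator of tubule repair, was at -0.60 ± 0.17. Of 19 proximal tubule genes in the count table, 6 passed the filter and were tested. Of these 6, 0 were called by edgeR, adjusted over the list alone or by DESeq2. Only 1, the bicarbonate cotransporter SLC4A4 (0.31 ± 0.13), had an unadjusted p under 0.05. GATM, of creatine synthesis, was at 0.33 ± 0.21. Of 19 genes of cisplatin transport and metallothioneins 0 were called by edgeR, adjusted over the list alone or by DESeq2, and 2 had an unadjusted p under 0.05, the zinc exporter SLC30A1 (-0.34 ± 0.11) and the copper exporter ATP7A (-0.34 ± 0.16). Without 0 h replicate 3, 2 genes of the kidney-injury list fell, and with the length correction 1 gene of that list fell and 1 proximal tubule gene rose. With the FPKM denominators 3 genes rose in the kidney-injury list, 1 in the proximal tubule list and 1 in the transport list.

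Genes of crosslink and excision repair, which remove platinum lesions, had 0 of 30 called by edgeR, adjusted over the list alone or by DESeq2, and 2 with an unadjusted p under 0.05, FANCI (0.30 ± 0.10) and the bypass polymerase POLH (-0.30 ± 0.12). Type I interferon genes had 0 of 21 called by the same 3 counts and 4 with an unadjusted p under 0.05, among them ISG15 (0.42 ± 0.17) and IFI44L (-0.39 ± 0.17). Immediate early genes had 0 of 24 called by the same counts and 6 with an unadjusted p under 0.05, led by the transcription factors ATF3 (-0.46 ± 0.15) and KLF4 (-0.49 ± 0.17). Their median (-0.01) and mean (-0.06) lay below 0 while camera's direction was up and fry's down. Heat-shock genes had 0 of 16 called by edgeR (1 higher adjusted over the list alone, 3 with an unadjusted p under 0.05, 1 by DESeq2), with the chaperone HSPB1 at 0.37 ± 0.10 and its partner BAG3 at -0.26 ± 0.10. Without 0 h replicate 3, 1 repair gene rose, 1 immediate early gene rose and 2 fell, and 1 heat-shock gene rose and 1 fell. With the FPKM denominators 2 repair, 5 interferon, 6 immediate early and 2 heat-shock genes rose.

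Cholesterol-synthesis genes had 0 of 24 called by edgeR (1 higher adjusted over the list alone, 5 with an unadjusted p under 0.05, 0 by DESeq2). LSS, lanosterol synthase, was at 0.30 ± 0.10. Camera's Benjamini-Hochberg adjusted p was 0.0771, 0.00483 without 0 h replicate 3 (4 rose), 0.0418 without 24 h replicate 2, 0.0141 without both libraries numbered 3 (2 rose) and 0.00964 with the FPKM denominators, where 9 rose. Ribosomal protein genes had 0 of 28 called by edgeR, adjusted over the list alone or by DESeq2, and 1 with an unadjusted p under 0.05, RPLP1 (0.27 ± 0.12), followed by RPS9 (0.26 ± 0.13). Camera's adjusted p for them was 0.121, 2.79e-04 without 0 h replicate 3 (1 rose), 0.00256 without 24 h replicate 1, 0.00157 without both libraries numbered 3 and 0.00784 with the FPKM denominators, where 7 rose. These values use the preset correlation of 0.01, and the one estimated for the ribosomal protein genes was 0.708. With an estimated correlation camera's adjusted p was 0.879 for ribosomal protein genes and 0.733 for cholesterol-synthesis genes. Ribosome-biogenesis genes had 0 of 24 called by the same 3 counts and 3 with an unadjusted p under 0.05, with BOP1 at 0.34 ± 0.13 and WDR12 at -0.30 ± 0.11, a median of -0.02 and a mean of 0.01, and 1 rose without 0 h replicate 3 and 4 with the FPKM denominators.

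**Figure D2:**
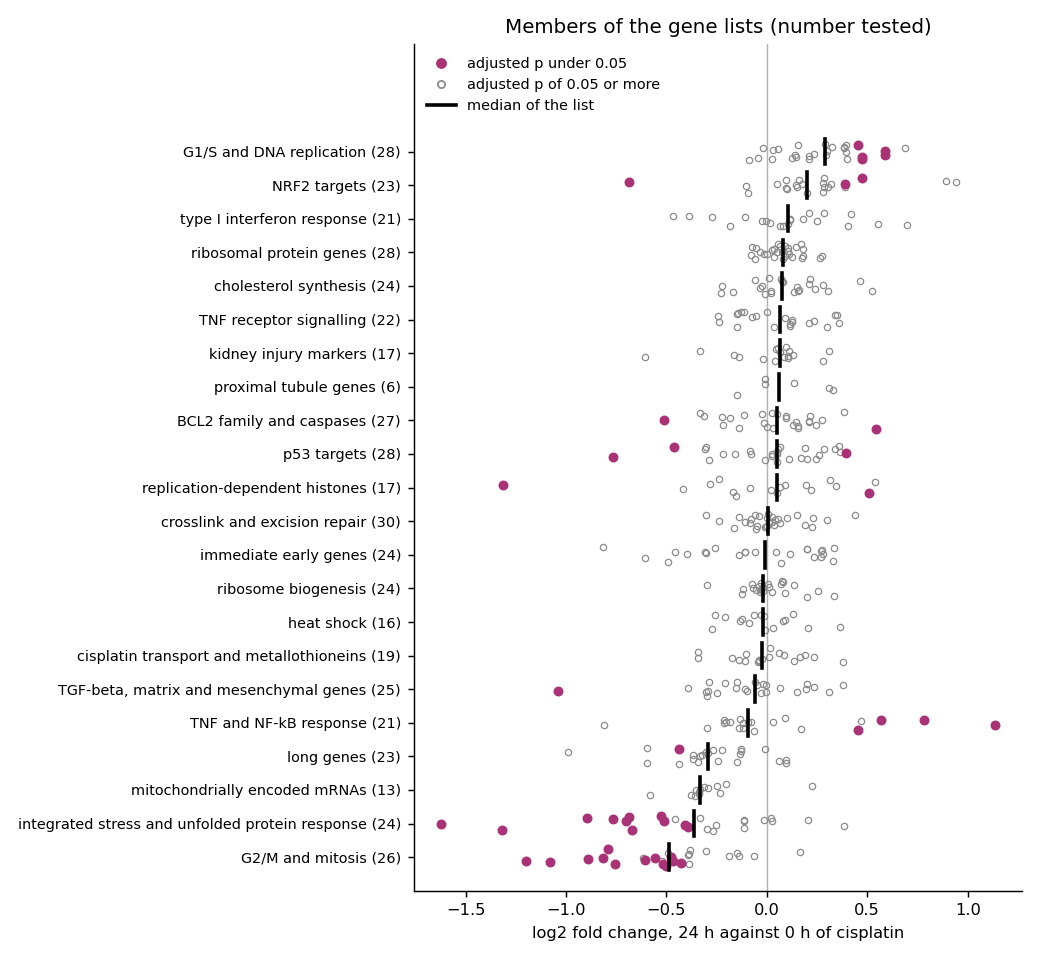
Log2 fold change of 24 h over 0 h of cisplatin for each tested member of the 22 lists, with members at an adjusted p under 0.05 filled and the median of each list as a black bar. Medians ran from -0.49 for G2/M and mitosis to 0.29 for G1/S and DNA replication, and with libraries scaled by the FPKM denominators these were -0.25 and 0.53.

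Markers of other cell types were few and none was called. Of the blood and immune list, 1 gene was tested, the macrophage marker CD68 (-0.16 ± 0.41), and the globin gene HBA1 was below the filter. Of endothelial genes 2 were tested, EGFL7 (-0.11 ± 0.15) and ERG (-0.16 ± 0.35), and of podocyte and distal nephron genes 3, with SYNPO at 0.14 ± 0.15, KRT7 at -0.08 ± 0.14 and the podocyte surface protein PODXL at -0.82 ± 0.28. By edgeR 0 of the 6 were called over all genes, 1 (PODXL, named after its value was seen) was lower adjusted over the list alone, 1 had an unadjusted p under 0.05, and DESeq2 called 0. The highest mean levels per list, over all 6 libraries, were 1.61, 14.6 and 45.6 CPM. The signs of CD68, EGFL7, ERG and KRT7 turned when libraries were scaled by the FPKM denominators.

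Genes with a long span had lower fold changes than short genes, a relation asked before the values were seen because platinum lesions block transcription. Spearman's rho across 13316 genes was -0.226, and -0.355 for genes above the median mean count. The 2664 genes with the shortest span (median 4272 bp) had a median log2 fold change of 0.08, with 43 rises and 61 falls, and the 2663 with the longest (158471 bp) had -0.10, with 13 rises and 71 falls. Of the 23 genes of the fixed list of long genes, 1 fell and 0 rose (adjusted over the list alone, 11 fell): VPS13B, a lipid-transfer protein (-0.44 ± 0.11), followed by the junction scaffold MAGI1 (-0.44 ± 0.12), which did not pass. The list's median was -0.29, or -0.06 with the FPKM denominators and -0.01 after the length correction, with camera's Benjamini-Hochberg adjusted p = 4.26e-05, fry's 0.0577, and adjusted p = 0.504 with an estimated correlation. VPS13B was not called by DESeq2, it was lost without any library other than 0 h replicate 3, and 5 of the list fell without that library.

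The relation with span was negative in each of the 9 pairs of a 24 h with a 0 h library, from -0.0659 to -0.264. Libraries of the same group also differed, by up to 0.200 in size between 24 h replicates 1 and 2. Without 24 h replicate 2 rho was -0.146. Fold changes were also related to GC content (rho 0.162), with rho from -0.315 to 0.528 over the 9 pairs, below 0 in 3 of them and highest with 0 h replicate 3.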

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

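All tests in this part were chosen after the result was seen. The FPKM values pointed to reads outside the gene table, a signal in data that no comparison above used. The gene table held 56.8 ± 0.994% of the FPKM denominator at 0 h and 66.5 ± 4.74% at 24 h (mean ± SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible). What the denominator counts is not given in the sources used here.

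Whether unspliced or intronic RNA made up the larger outside share at 0 h stays open. Counts of sense-intronic loci, scaled to the denominator as CPM, went from 490 ± 81.9 to 552 ± 53.4 (mean ± SD, n = 3 each, ratio 1.13), where a fall in proportion to the outside share would have given 379, but these loci lie inside the gene table and do not measure the reads outside it, 0 h replicate 3 was at 396, and as a share of all counts they were at 0.0865% and 0.0828%. Whether ribosomal RNA was part of it stays open too. Mitochondrial rRNA went from 5141 ± 1990 to 2756 ± 656 on that scale (ratio 0.536), and genes inside 18S, 5.8S or 28S loci from 42.3 ± 3.30 to 25.3 ± 4.04. All 3 libraries at 24 h lay below all 3 at 0 h in each class (exact two-sided permutation p = 0.1 each, n = 3). These rRNA genes also lie inside the gene table, so their counts do not measure the reads outside it. Against a close link, 0 h replicate 3 had the highest mitochondrial rRNA (7438) and the smallest outside share of the 0 h libraries, and the 2 genes in the 45S spacers had a ratio of 1.42 (exact two-sided permutation p = 0.5, n = 3). A change in rRNA depletion and a change in the cells cannot be told apart with these libraries, and the time of cisplatin stays open as an untested biological explanation.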

How the results depend on the processing

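The GC correction, protein-coding genes alone, removal of both libraries numbered 3 and scaling by the FPKM denominators were tests chosen after the result was seen. Against 116 genes higher at 24 h and 278 lower, RLE, upper-quartile and total-count scaling, a filter at 1 CPM, robust dispersion, the length correction, removal of the 10 most abundant genes, protein-coding genes alone and DESeq2 gave 106 to 125 higher and 213 to 277 lower. With no filter 345 were higher, with the GC correction 312 and 459, without both libraries numbered 3 306 and 539, with the FPKM denominators 2354 higher, and with limma on log2(FPKM + 1) 1657 and 138. The FPKM scale moves all genes together where the gene table holds a different share of the denominator, here 56.8% at 0 h and 66.5% at 24 h. The cause of the other differences was not tested. A 2-fold minimum, which by construction removes calls, left 6 and 98. Leaving out 1 library gave 21 to 574 higher and 92 to 923 lower, 6 to 9 called lists, and -0.237 to -0.146 for the relation of fold change to gene length, which was -0.355 for genes above the median mean count. The cause was not tested. The replicate number as a block gave 739 and 959, and 561 and 745 with the length correction. Whether the numbers pair the samples is not settled, and the labels state no pairing. Deviations of same-numbered libraries correlated at 0.241, -0.0199 and 0.422. Each library numbered 1 or 3 correlated best with its same-numbered partner, but both libraries numbered 2 correlated best with number 1. With the block, 7 mitochondrially encoded mRNAs and 9 long genes fell, and 0 interferon, proximal tubule and ribosomal protein genes were called. Called lists went from 6 to 0 by camera with an estimated correlation (4 at an unadjusted p under 0.05) and to 4 by fry, and 5 to 8 were called in the other fits with all libraries or without both numbered 3. List tests that turned direction, all with adjusted p over 0.05, are given as camera's Benjamini-Hochberg adjusted p, or fry's for immediate early genes (0.962). They were p53 targets 0.937, immediate early genes 0.702 and long genes 0.942 with the length correction, immediate early genes 0.712 and histones 0.903 with the GC correction, heat shock 0.597 and cisplatin transport 0.834 with the FPKM denominators, and heat shock 0.848 and cisplatin transport 0.841 without both libraries numbered 3. Without 1 library the adjusted p ran from 0.0336 to 0.898 for histones, 0.420 to 0.960 for heat shock, 0.606 to 0.986 for immediate early genes, 0.585 to 0.986 for cisplatin transport, 0.585 to 0.940 for crosslink repair and 0.312 to 0.897 for ribosome biogenesis, and each turned direction in at least 1 such fit. The cause was not tested, except that the length correction removes the long-gene trend by construction. Of the named genes, only markers of other cell types turned sign. Without 1 library the log2 fold change ran from -0.0056 to 0.29 for SYNPO, -0.50 to 0.039 for CD68 and -0.20 to 0.0091 for KRT7. Without both libraries numbered 3, CD68 was at 0.072, ERG at 0.070 and KRT7 at 0.082, with the FPKM denominators CD68 was at 0.078, EGFL7 at 0.13, ERG at 0.078 and KRT7 at 0.16, and with limma CD68 was at 0.021, EGFL7 at 0.097, ERG at 0.011 and KRT7 at 0.15. The cause was not tested. Across all alternatives the other comparisons of named genes with the values reported kept direction, 1109 on the same side of the threshold, 86 newly called and 66 no longer called, and for lists these were 288, 10 and 9. At this depth the edgeR test recovered 42.4% of simulated 1.5-fold changes, so smaller changes of single genes were often not detectable.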

Other observations

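All tests in this part were chosen after the result was seen, except that of transcript length against gene span. The single genes in this paragraph lie outside the fixed lists, passed edgeR's quasi-likelihood test and were chosen after their values were seen, so they are examples and not a tested group. Among amino-acid transporters, SLC1A4 (-1.14 ± 0.14 on the log2 scale), SLC7A5 (-0.94 ± 0.16), SLC7A1 (-0.70 ± 0.13) and SLC38A1 (-0.67 ± 0.10) fell. So did CTH, of cysteine synthesis (-1.10 ± 0.13), PSPH, of serine synthesis (-0.69 ± 0.10), the alanine transaminase GPT2 (-0.73 ± 0.11), the folate enzymes ALDH1L2 (-0.95 ± 0.20), SHMT2 (-0.60 ± 0.10) and MTHFD2 (-0.53 ± 0.11), and the stress regulator NUPR1 (-1.86 ± 0.39). NUPR1 was not among the largest falls named above because it missed the naming rule's limit on level or on overlap between the groups. The thymidine kinase TK1 rose by 0.64 ± 0.10, PKMYT1, an inhibitor of entry into mitosis, by 0.69 ± 0.16, and the checkpoint adaptor CLSPN by 0.48 ± 0.11. Tissue factor F3 (0.88 ± 0.12), the cell-cycle inhibitor SFN (0.86 ± 0.12) and the mitophagy receptor BNIP3 (0.72 ± 0.11) also rose.

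Cytosolic tRNA synthetases, which load amino acids on tRNA, fell in part: of 20 tested, 8 fell and 0 rose by edgeR, with 12 at an unadjusted p under 0.05 and 8 called by DESeq2. Examples are WARS (-0.81 ± 0.10), GARS (-0.76 ± 0.10) and YARS (-0.70 ± 0.10), and the median was -0.34. GARS and KARS were placed in the cytosolic set, and the mitochondrial set held no separate counterpart of either. Of 17 mitochondrial synthetases 0 were called by edgeR or DESeq2, 2 had an unadjusted p under 0.05, and the median was 0.02. The medians differed by -0.36, but the cytosolic family was taken up after its fall was seen, so the permutation test across genes (two-sided p = 0.01305) restates that choice and whether the fall is specific to the cytosolic set stays open. The 8 falls became 5 without 0 h replicate 2, 4 without 24 h replicate 2 and 5 without 24 h replicate 3, and with libraries scaled by the FPKM denominators 4 cytosolic genes rose and 3 fell, 2 mitochondrial genes rose, and the medians were -0.10 and 0.25.

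Ribosomal RNA genes, whose copies make them uncertain, were lower at 24 h relative to the median gene. The mitochondrial rRNA genes MT-RNR1 (-1.16 ± 0.22 on the log2 scale) and MT-RNR2 (-1.10 ± 0.24) fell. Of 6 genes inside 18S, 5.8S or 28S loci of chromosome 21, 4 fell, and CH507-513H4.3, CH507-513H4.4 and CH507-513H4.6 were at -1.84 ± 0.26, -1.59 ± 0.27 and -1.67 ± 0.27. The 2 genes in the 45S spacers, MIR3648-1 (0.27 ± 0.37) and MIR3687-1 (0.47 ± 0.49), were above 0 and not called.

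Lower genes of the integrated stress response and of mitosis with higher genes of G1/S comprised 29 called members of 3 lists. Of these, 28 were still called after the length correction, 29 after the GC correction of each library and 28 without 0 h replicate 3. Of all 394 called genes, these fits kept 310, 386 and 392. The first count argues against gene length as the whole cause of the 29 calls. The other 2 counts were near those of all called genes, and the 29 were picked by their calls in these data. They therefore do not decide on GC bias or 1 deviating library for these lists. All 29 kept their sign under each alternative run, but 22 were called without 0 h replicate 1, 14 without 0 h replicate 2, 17 without 24 h replicate 1, 16 without 24 h replicate 2, 17 without 24 h replicate 3 and 19 with the FPKM denominators. Time after transfection, with its changes of density and medium, and cisplatin cannot be told apart, because 0 libraries kept for 24 h without cisplatin were analysed here. For the count of genes, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 394 genes and any other at most 4. For the count of lists, 4 of the 10 splits, the real one included, called at least the 6 lists of the real split. The highest other called 7. The number of lists called at the preset correlation therefore does not set the real split apart.

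Lower fold changes of genes with a long span may come from blocked transcription or from differences in RNA fragments between libraries. The partial Spearman correlation with span given exon length was -0.125 and that with exon length given span was -0.0862, and the former was positive in 2 of 9 pairs of libraries, so the relation with span and that with transcript length cannot be told apart. Ordinary variation between libraries stays open too, since 24 h replicates 1 and 2 differed by a correlation of 0.200 in size, against 0.226 between the groups. The 10 splits are too few for a share under 0.05, with 0.226 in size for the real split and 0.212 for the highest other.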
